A study of Mus musculus with 6 samples.

How the data were processed

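The series holds 6 arrays of callus RNA from mice at day 14 after a stabilised tibial osteotomy, 3 from Cyp24a1-null mice and 3 from heterozygous littermates. Per the labels' protocols, callus was kept in a preservative, total RNA was extracted with Trizol and a column kit, biotin-labelled and hybridised to the Affymetrix Mouse 430_2 array. The deposited table gives one value per probe set and array, which from its range (1.65 to 14.49 over all arrays, medians 4.55 to 4.59) was taken to be log2. The software, background correction, summarisation and normalisation behind these log2 values are not given in the sources used here. The columns have nearly the same distribution, so a shift of all genes together would have been removed before deposit, and summarised low values lie close to a floor, which compresses differences of weakly expressed genes.

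Of the 45101 probe sets in the deposited table, 64 control probe sets were left out of all tests. Gene symbols came from the platform annotation supplied with the table, where 34945 probe sets have 1 symbol, 932 have several and 9160 have none listed. Probe sets with several or no symbols were tested and named only by their identifier. Symbols of 18032 genes were matched by gene identifier to a RefSeq gene table on the assembly GRCm38.p6, which changed 0 of them. That table served for names and for which genes neighbour each other, and none of its coordinates are printed because the deposited table names no genome build. For gene lists and neighbours, each gene was represented by the probe set with the highest mean over the 6 arrays, chosen without the groups, which gave 18193 genes. Probe sets disagreed in direction for some named genes besides those so marked in the text: 3 of 4 had the direction given for Cd44, Col12a1 and Adamts5, 2 of 3 for Cxcl12 and Cyp51, 5 of 6 for Plxnc1, 2 of 4 for Tpx2 and 1 of 2 for Erg.

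Each probe set was tested on the log2 values as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means, two-sided), with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05 on the adjusted p. The direction is always null minus heterozygous. The residual degrees of freedom were 4, the prior added 2.50, and the median SE of a difference was 0.15. No filter on level, covariate or litter term entered the fit. For 3 against 3 arrays the smallest two-sided exact permutation p is 0.1. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 35 lists, and beside it with camera at an estimated correlation and with fry. Camera compares a list with all other genes, fry's directional test asks whether a list's own genes move one way on balance, and its mixed test, which passed 0 lists (lowest adjusted p = 0.417), asks whether they change in either direction. The lists covered vitamin D and sphingolipid metabolism, cartilage, bone, marrow, blood, vessel, muscle, fat, skin, tendon and nerve cell types, signalling pathways, inflammation, metabolism and handling stress. They sought 951 members, of which 884 were measured on a probe set with 1 symbol. Members not measured in this way include Runx2, Spp1, Bglap, Phospho1 and Enpp1, which are not analysed here. A further list of sex-linked transcripts was described per array and not tested.

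The rule for naming genes, the lists, the tests and the first set of alternatives were fixed before the data were examined. Cyp24a1 and Fam57b (Tlcd3b) were named by rule with all probe sets. Up to 12 genes in each direction were to be those passing the test with the largest change. Places left were filled, as all of them were here, by genes with the lowest unadjusted p in that direction, without overlap of the groups and with a mean level above the median of all probe sets, leaving out predicted transcripts and immunoglobulin and T cell receptor segments. In each list, up to 4 members with the lowest unadjusted p were eligible. The levels of Xist and Y-linked probe sets on arrays without the transcript, used as a guide to values not above background, were chosen after the values were seen. Where every array of a group lay at or under the highest of them, only a bound on the fold against that level is given. For Cyp24a1, named by rule, the differences are printed beside the bounds. S100a8, Slc4a1, Acta1, Ckm, Col1a1 and Ctsk, given as level markers, and the unnamed probe set 1447360_at were chosen after their values were seen.

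Other settings, chosen in advance, were quantile and cyclic loess normalisation of the deposited values, centring arrays on their medians, array weights, an intensity trend with a robust prior, a filter at the median level, 1 probe set per gene, other thresholds, a plain test with equal variances, other ways of representing or testing lists, other windows around Cyp24a1, and leaving out each array. Pseudocounts were planned only for linear values and do not apply. A marrow score (the mean of the neutrophil and erythroid genes per array) as a covariate, and the fit without null replicate 1 and heterozygous replicate 3, were added after seeing the data, as were a list of denervated or regenerating muscle genes and a list of simple epithelial genes. The labels give no litter, batch or scan date.

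The fits were tested on simulated data with the real probe sets' means and spreads and 200 changed probe sets among 45037. The changed probe sets were drawn from those above the median level, and the noise was independent between probe sets. With 3 against 3 arrays, 26.9% of 67 probe sets changed by 1 on the log2 scale, 85.1% of 67 changed by 2 and 89.4% of 66 changed by 3 were recovered, with 7 false calls. With no change simulated there were 0 calls and 5.48% of probe sets had an unadjusted p under 0.05. A shifted list was called and 0 others were. The simulated genes varied independently, so this does not test camera on lists whose genes move together. In the real data the estimated correlation was 0.98 for the neutrophil list and 0.39 for the macrophage list.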

Results

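Gene expression was compared in healing bone of mice lacking Cyp24a1, the 24-hydroxylase that breaks down active vitamin D, and of their heterozygous littermates. Mice aged 12 weeks, of a C57BL6J x 129SV mixed background, had the tibia cut and stabilised with a rod in the marrow cavity, and the callus, the repair tissue at the break, was taken at day 14. Total RNA was biotin-labelled and hybridised to Affymetrix Mouse 430_2 arrays, with 3 null and 3 heterozygous arrays and 45037 probe sets per array after control probe sets were left out. The array medians lay between 4.55 and 4.59 on the log2 scale, and Pearson's r between arrays, computed across probe sets, ran from 0.970 to 0.991. The number of arrays limits the precision, and the labels do not say that each sample came from a separate mouse, so the p-values measure the spread between these samples.

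Cyp24a1 was measured at a low level in both groups. Its values lay mostly within those of sex-linked transcripts on arrays without them (1.77 to 3.52), so the differences below are not shown to lie above background. Probe set 1418866_at averaged 3.36 ± 0.25 (SD, n = 3) in null callus and 2.90 ± 0.19 (SD, n = 3) in heterozygous callus. The null minus heterozygous difference was 0.46 (SE 0.17), and its null values lay above all heterozygous values. All 3 heterozygous values and 2 of the 3 null values lay under 3.52, which leaves a bound of 1.029-fold higher in null callus. Probe set 1418867_at averaged 3.27 ± 0.17 (SD, n = 3) and 3.34 ± 0.30 (SD, n = 3), a difference of -0.07 (SE 0.18). Here all 3 null values lay under 3.52, which leaves a bound of 1.04-fold higher in heterozygous callus. The mean levels lay at percentiles 27.9 and 32.0 of all probe sets. Neither probe set passed limma's test (adjusted p = 0.999 for both), and the two-sided exact permutation p was 0.1 for 1418866_at, the smallest that 3 against 3 arrays allow, and 0.8 for 1418867_at. The sign for 1418867_at turned without null replicate 3 (0.0025) and without heterozygous replicate 2 (0.10). Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so the values do not check the genotype labels.

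The question put to all probe sets was which transcripts differ in callus when Cyp24a1 is absent. Krt8 and Krt18, the paired keratins of simple epithelia, had lower levels in null callus. Krt8 (1423691_x_at) averaged 7.01 ± 0.58 (SD, n = 3) in null and 9.64 ± 0.23 (SD, n = 3) in heterozygous callus, a difference of -2.63 (SE 0.30) and a 6.20-fold higher heterozygous level, with the same direction on all 3 of its probe sets. Krt18 (1448169_at) averaged 7.79 ± 0.64 (SD, n = 3) and 10.52 ± 0.34 (SD, n = 3), a difference of -2.73 (SE 0.34) or 6.63-fold. Eda2r, a receptor of the tumour necrosis factor receptor family, averaged 8.37 ± 0.36 and 9.64 ± 0.14 (difference -1.28, SE 0.19), and Atp13a3, a P5-type transport ATPase, averaged 9.06 ± 0.44 and 10.44 ± 0.13 (difference -1.38, SE 0.22). Sh3d19 differed by -1.39 (SE 0.22) and Mtss2 by -1.28 (SE 0.21). The semaphorin Sema4d differed by -0.99 (SE 0.16), with 1 of its 3 probe sets in the other direction. The transcriptional repressor Bcl6 differed by -0.90 (SE 0.14) and the potassium channel subunit Kcnq5 by -0.91 (SE 0.14). Mapk4, Dapk2 and Ypel2 completed the 12 genes named on the lower side, at -0.86, -0.76 and -0.58.

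On the higher side, the chemokine Cxcl1 (1419209_at) averaged 5.67 ± 0.16 (SD, n = 3) in null and 4.29 ± 0.27 (SD, n = 3) in heterozygous callus, a difference of 1.37 (SE 0.17) or 2.59-fold, and all 3 of its probe sets had the same direction. The extracellular matrix gene Tnn, which encodes tenascin-N, averaged 6.91 ± 0.44 and 5.66 ± 0.17 (difference 1.25, SE 0.23). The myelin protein gene Pmp22 averaged 10.24 ± 0.14 and 9.37 ± 0.28 (difference 0.86, SE 0.17), and Pla2g7, which encodes the platelet-activating factor acetylhydrolase of plasma, averaged 8.80 ± 0.15 and 8.05 ± 0.02 (difference 0.75, SE 0.11). The kinase gene Prkcd differed by 0.65 and the membrane glycoprotein gene Gpm6b by 0.75. Mylk, Als2cl, St6gal1, Vav3, Plxnc1 and Sec63 had differences from 0.45 to 0.53. For Sec63, 2 of 5 probe sets had the direction of the named one, and for St6gal1, 1 of 2.

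In all these genes the 3 null values lay on one side of the 3 heterozygous values, because the rule for naming them required it. No probe set passed limma's test at an adjusted p of 0.05, and the lowest adjusted p was 0.775. An unadjusted p under 0.05 was reached by 1660 probe sets, 732 higher and 928 lower in null callus. They were 3.69% of those tested, below the 5% expected by chance, and 310 of them differed by at least 1.5-fold. The count depended on the setting. With 2252 expected by chance, it was 3552 with the marrow score as a covariate and 3453 without null replicate 1 and heterozygous replicate 3. Both settings were chosen after seeing the data. The count was 1048 without null replicate 3 and 1062 without heterozygous replicate 1. The groups did not overlap in 8.95% of probe sets, against 10% by chance for 3 against 3 arrays. A plain test per probe set with equal variances also left 0 passing, with 1942 at the unadjusted threshold. In simulated data of this size, limma recovered 26.9% of genes changed by 1 on the log2 scale and 85.1% of those changed by 2. That simulation planted 200 changes above the median level with independent noise, so these shares need not hold for the real arrays.

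**Figure D1:**
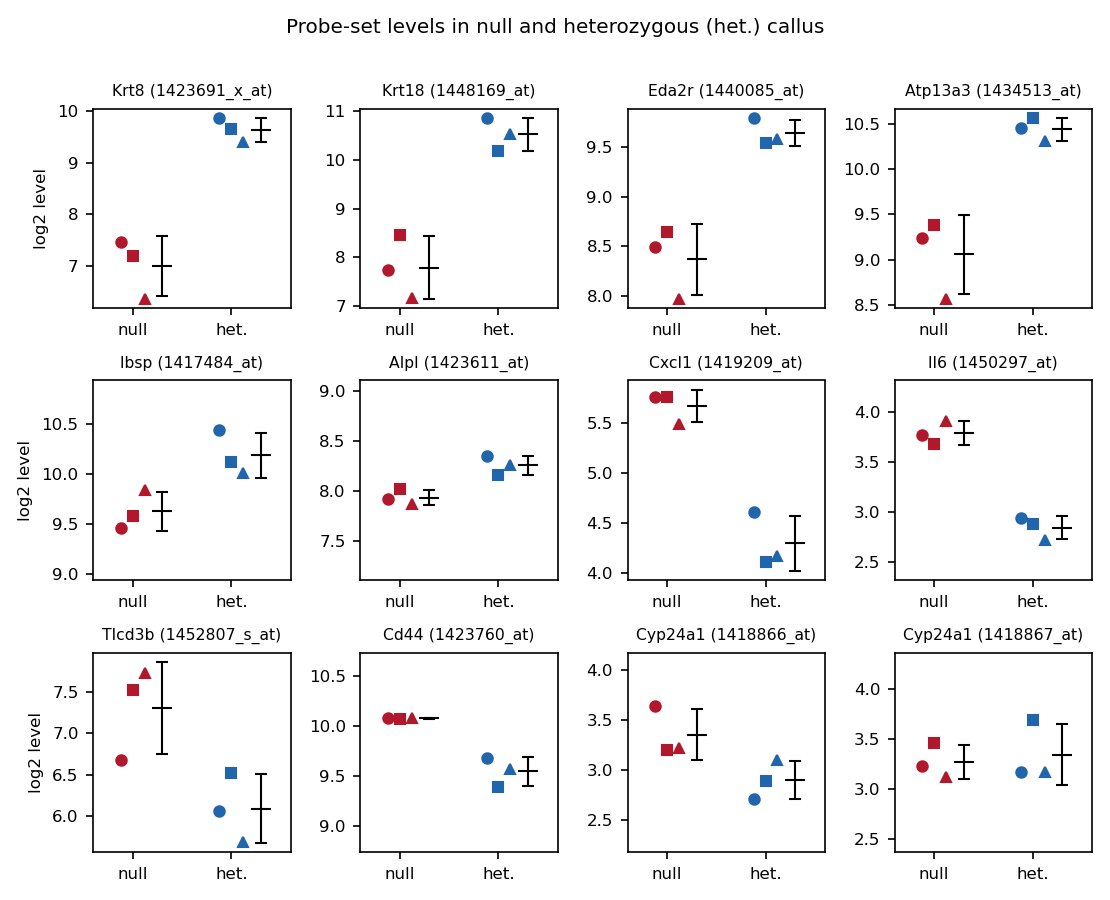
Log2 levels (vertical axes) of 12 probe sets in null callus (red) and heterozygous callus (blue), with a circle, square and triangle for replicates 1, 2 and 3 and a black mark with bars for the mean and SD of the 3 arrays. Krt8 and Krt18 lie more than 2 log2 units apart between the group means, the Cxcl1 and Il6 values do not overlap between groups, and the Cyp24a1 probe sets lie below a level of 4.

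Tlcd3b, listed on older arrays as Fam57b and coding for a ceramide synthase of the endoplasmic reticulum, was named in advance because published work on this mouse line concerns it, so neither it nor the sphingolipid list is independent evidence of a direction. Its probe set 1452807_s_at averaged 7.31 ± 0.56 (SD, n = 3) in null and 6.09 ± 0.41 (SD, n = 3) in heterozygous callus, a difference of 1.22 (SE 0.33) or 2.33-fold, without overlap of the groups. Probe sets 1452806_at and 1438641_x_at differed by 1.02 (SE 0.37) and 0.82 (SE 0.51), the latter by 1.41 without null replicate 1 and 0.43 without null replicate 3, and 1454209_at, at a mean level near 4, by -0.09 (SE 0.17). None of the 4 passed limma's test (adjusted p = 0.999 for each). Of the 33 measured genes of ceramide and sphingolipid metabolism, 24 were higher in null callus, 5 of them at an unadjusted p under 0.05, and 0 passed either adjusted over all probe sets or adjusted over the list alone. The median difference of the list was 0.20, and the list rose as a group in limma's camera test with a preset correlation of 0.01 (adjusted p = 0.00585; adjusted p = 0.568 with an estimated correlation). Among its members, the sphingosine-1-phosphate phosphatase Sgpp1 differed by 0.39 (SE 0.13) and the ceramide synthase Cers2 by 0.26 (SE 0.10). The list's median was 0.095 without null replicate 1, and its call was lost without heterozygous replicate 2 (adjusted p = 0.0608), and with genes under the median level left out (adjusted p = 0.0694). The vitamin D metabolism and signalling list, with 14 of 20 genes higher in null callus and a median of 0.06, did not pass (adjusted p = 0.343). Its member Klk6, a kallikrein, differed by 1.02 (SE 0.32).

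The cell makeup of the callus was described with marker lists fixed before the data were examined. Genes of bone marrow were low on null replicate 1 and heterozygous replicate 3. The mean of the neutrophil and granulocyte precursor genes, relative to each gene's mean over the 6 arrays, was -2.40 and -3.00 there and lay between 1.12 and 1.67 on the other 4 arrays. The erythroid genes gave -2.07 and -1.84 there, against 0.49 to 1.28. The neutrophil alarmin S100a8 was at 10.16 and 9.25 on these arrays and between 13.01 and 13.25 on the other 4, and the red cell anion exchanger Slc4a1 was at 3.06 and 4.89 against 10.03 to 10.72. The first principal component of the arrays, with 53.7% of the variance, separated these 2 arrays from the rest. Each group held 1 of them, and the neutrophil (median 0.27, adjusted p = 0.520), erythroid (median -0.24, adjusted p = 0.520), megakaryocyte and platelet (0.15, adjusted p = 0.279), B cell and plasma cell (0.10, adjusted p = 0.319) and haematopoietic progenitor lists (0.13, adjusted p = 0.0968) did not pass camera. Neither did the T and NK cell list (adjusted p = 0.826), whose median (-0.07) and mean (0.07) differ in sign. The nerve and Schwann cell list did not pass either (0.15, adjusted p = 0.0968). Its member Pmp22 passed limma's test when adjusted over the list alone (adjusted p = 0.0195), but not over all probe sets (adjusted p = 0.999). Skeletal muscle transcripts were abundant on every array, with the actin gene Acta1 between 14.40 and 14.49 and the creatine kinase gene Ckm between 13.60 and 14.10, and that list did not pass (median -0.13, adjusted p = 0.0884). The adipocyte (0.17, adjusted p = 0.474) and smooth muscle and pericyte lists (0.19, adjusted p = 0.0501) did not pass. These results depended on single arrays. Without null replicate 1 the neutrophil (median 1.59, adjusted p = 0.000430), erythroid (0.78, adjusted p = 0.0237), megakaryocyte (0.46, adjusted p = 0.00176), B cell (0.33, adjusted p = 0.00444), progenitor (0.33, adjusted p = 0.00197), nerve (0.30, adjusted p = 0.000899), smooth muscle (0.29, adjusted p = 0.00142) and adipocyte lists (0.16, adjusted p = 0.0417) passed upward. Without heterozygous replicate 3 the neutrophil (-1.26, adjusted p = 0.00552), erythroid (-1.17, adjusted p = 0.000751) and skeletal muscle lists (-0.19, adjusted p = 0.00444) passed downward, and the adipocyte (0.49, adjusted p = 4.71e-06) and smooth muscle lists (0.38, adjusted p = 0.00552) upward. Without heterozygous replicate 1 the neutrophil (1.01), megakaryocyte (0.41) and progenitor lists (0.25) passed upward. Without null replicate 2 the erythroid (-0.79) and skeletal muscle lists (-0.17) passed downward, and without null replicate 3 the skeletal muscle list (-0.19) downward. Sex-linked transcripts had list means of -1.09 on null replicate 1 and -1.004 on heterozygous replicate 1, and 0.44 to 0.62 on the other 4 arrays, so that each group held 1 array with high Xist and low Y-linked transcripts.

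**Figure D2:**
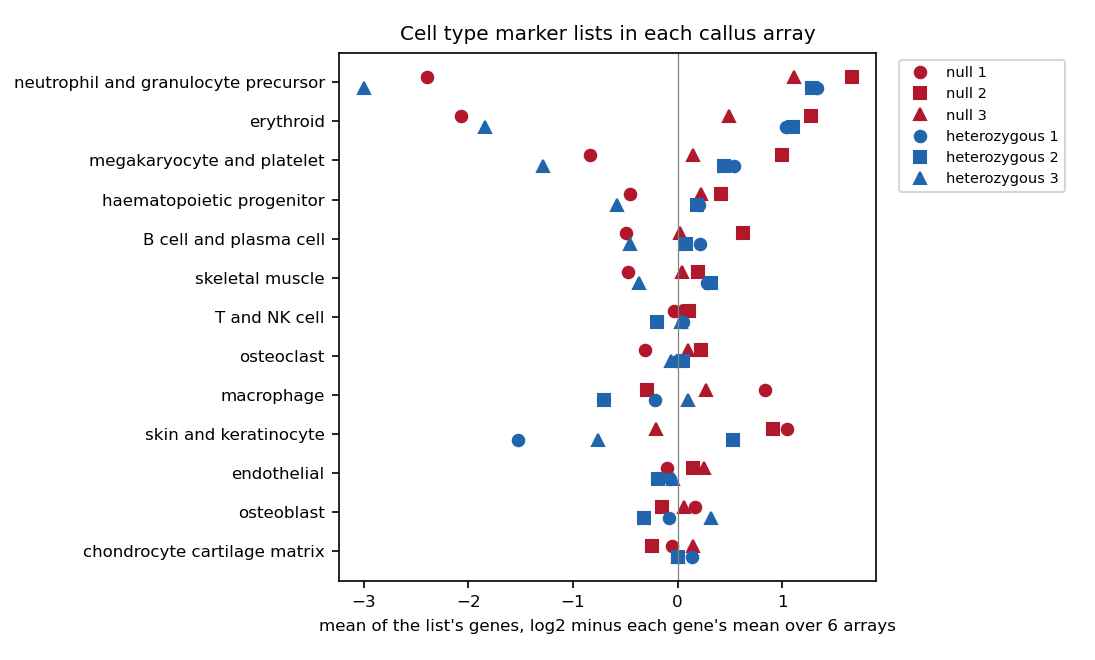
Mean of each marker list on each array (horizontal axis, log2 relative to each gene's mean over the 6 arrays), with null arrays in red, heterozygous arrays in blue, and circle, square and triangle for replicates 1, 2 and 3. Null replicate 1 and heterozygous replicate 3 lie below -1.8 for the neutrophil and erythroid lists, while the other 4 arrays lie above 0.4.

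Of the 35 lists tested, 10 passed camera with the preset correlation, all of them higher in null callus. Inflammatory cytokines and chemokines rose as a group, with 26 of 32 genes higher in null callus, a median difference of 0.50 or 1.42-fold, and 7 genes at an unadjusted p under 0.05, all higher (adjusted p = 3.26e-09; adjusted p = 0.568 with an estimated correlation). Il6 averaged 3.79 ± 0.12 (SD, n = 3) in null and 2.84 ± 0.12 (SD, n = 3) in heterozygous callus. The heterozygous values were not above the level of silent transcripts (up to 3.52). Against 3.52 the null mean was 1.20-fold higher, a bound that takes its level from other probe sets and carries no measure of error. Il6 passed when adjusted over the list alone (adjusted p = 0.00400), as did Cxcl1 on the list's probe set 1457644_s_at (0.52, SE 0.11, adjusted p = 0.0398). Neither passed limma's test adjusted over all probe sets (adjusted p = 0.775 and 0.999). The adjustment within a list was not corrected for the 35 lists. The chemokine Cxcl12 differed by 0.57 (SE 0.19). The inflammatory list means of the arrays overlapped between groups, at 0.63, -0.16 and 0.27 in null and -0.07, -0.43 and -0.24 in heterozygous callus. The median was 0.30 without null replicate 1 and 0.32 without heterozygous replicate 2. Macrophage genes rose as a group, with all 24 measured genes higher in null callus and a median of 0.47 (adjusted p = 1.04e-06; adjusted p = 0.692 with an estimated correlation). The scavenger receptor genes Mrc1 and Cd163 differed by 0.86 (SE 0.30) and 1.19 (SE 0.43), and the lysozyme gene Lyz2 by 0.58 (SE 0.24; 0.34 without heterozygous replicate 2). The macrophage list means overlapped between groups, at 0.84, -0.30 and 0.27 in null and -0.21, -0.70 and 0.10 in heterozygous callus. The median was 0.19 without null replicate 1, 0.80 without null replicate 2, 0.25 without heterozygous replicate 2 and 0.79 without heterozygous replicate 3. Skin and keratinocyte genes also rose as a group, with 15 of 16 higher and a median of 1.27 or 2.42-fold (adjusted p = 2.04e-06; adjusted p = 0.692 with an estimated correlation). Their list means overlapped too, at 1.05, 0.91 and -0.21 in null and -1.53, 0.53 and -0.76 in heterozygous callus. The median was 0.75 without heterozygous replicate 1. Of the 10 lists, only ceramide and sphingolipid metabolism had array means without overlap of the groups (two-sided exact permutation p = 0.1). For any 1 list this has a chance of 10% with 3 against 3 arrays, so it does not set that list apart. The epidermal gene Krtdap differed by 1.81 (SE 0.63), and the basal keratin gene Krt5 by 1.30 (SE 0.59), or by 1.20 and 0.78 without heterozygous replicate 1.

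Cell cycle genes were higher in null callus in 33 of 35 cases, with a median of 0.32, and rose as a group (adjusted p = 3.85e-05; adjusted p = 0.692 with an estimated correlation). The DNA helicase gene Hells differed by 0.24 (SE 0.11) and the spindle gene Tpx2 by 0.54 (SE 0.28; 0.25 without heterozygous replicate 3). Its lowest mean, -0.82, was on heterozygous replicate 3, and its mean on null replicate 1, the other marrow-poor array, was 0.08. Its call was lost with array weights (median 0.021, adjusted p = 0.684), without null replicate 2 (0.14, adjusted p = 0.144) and without both marrow-poor arrays (0.020, adjusted p = 0.663), and the median was -0.0066 without heterozygous replicate 3 (adjusted p = 0.998). It was 0.49 without null replicate 3, 0.53 without heterozygous replicate 1 and 0.51 without heterozygous replicate 2. Cholesterol and fatty acid synthesis genes rose as a group, 20 of 25 higher, median 0.23 (adjusted p = 0.000244; adjusted p = 0.683 with an estimated correlation). The lipogenic enzyme genes Acly and Elovl6 differed by 0.56 (SE 0.16) and 0.84 (SE 0.33; 0.45 without null replicate 2), and the sterol demethylase gene Cyp51 by 0.39 (SE 0.13). Hypoxia and glycolysis genes rose as a group, 22 of 29 higher, median 0.24 (adjusted p = 0.000652; adjusted p = 0.568 with an estimated correlation), with a median of 0.16 without null replicate 3, Ndrg1 at 0.34 (SE 0.14) and the carbonic anhydrase gene Car9 at 0.41 (SE 0.20; 0.22 without null replicate 1). Tendon and fibroblast genes rose as a group, 18 of 21 higher, median 0.32 (adjusted p = 0.000836; adjusted p = 0.692 with an estimated correlation), with the collagen gene Col12a1 at 0.96 (SE 0.33) and the proteoglycan gene Fmod at 0.42 (SE 0.19; 0.26 without null replicate 3). Endothelial genes rose as a group, 22 of 24 higher, median 0.20 (adjusted p = 0.00139; adjusted p = 0.692 with an estimated correlation), with the transcription factor gene Erg at 0.36 (SE 0.15). Matrix-degrading enzymes and inhibitors rose as a group, 22 of 26 higher, median 0.17 (adjusted p = 0.0217; adjusted p = 0.692 with an estimated correlation), with the aggrecanase gene Adamts5 at 0.57 (SE 0.21; 0.34 without null replicate 3). The tendon and endothelial calls were lost without null replicate 3 (adjusted p = 0.137 and 0.0681) and without heterozygous replicate 2 (adjusted p = 0.114 and 0.1003), and without heterozygous replicate 3 their medians were 0.49 and 0.34. The matrix-degrading call was lost without either of these (adjusted p = 0.115 and 0.227), without heterozygous replicate 1 (adjusted p = 0.246), and with genes under the median level left out (adjusted p = 0.0571), and its median was 0.33 without null replicate 2 and 0.39 without heterozygous replicate 3.

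With an estimated correlation between genes of a list, 0 lists passed camera, and 3 had an unadjusted p under 0.05. The fry test also left 0 lists, with 1 at the unadjusted threshold. The count of 10 lists became 19 without both marrow-poor arrays, where 9 of the 10 were shared, 21 without null replicate 1 and 19 without heterozygous replicate 3.

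**Figure D3:**
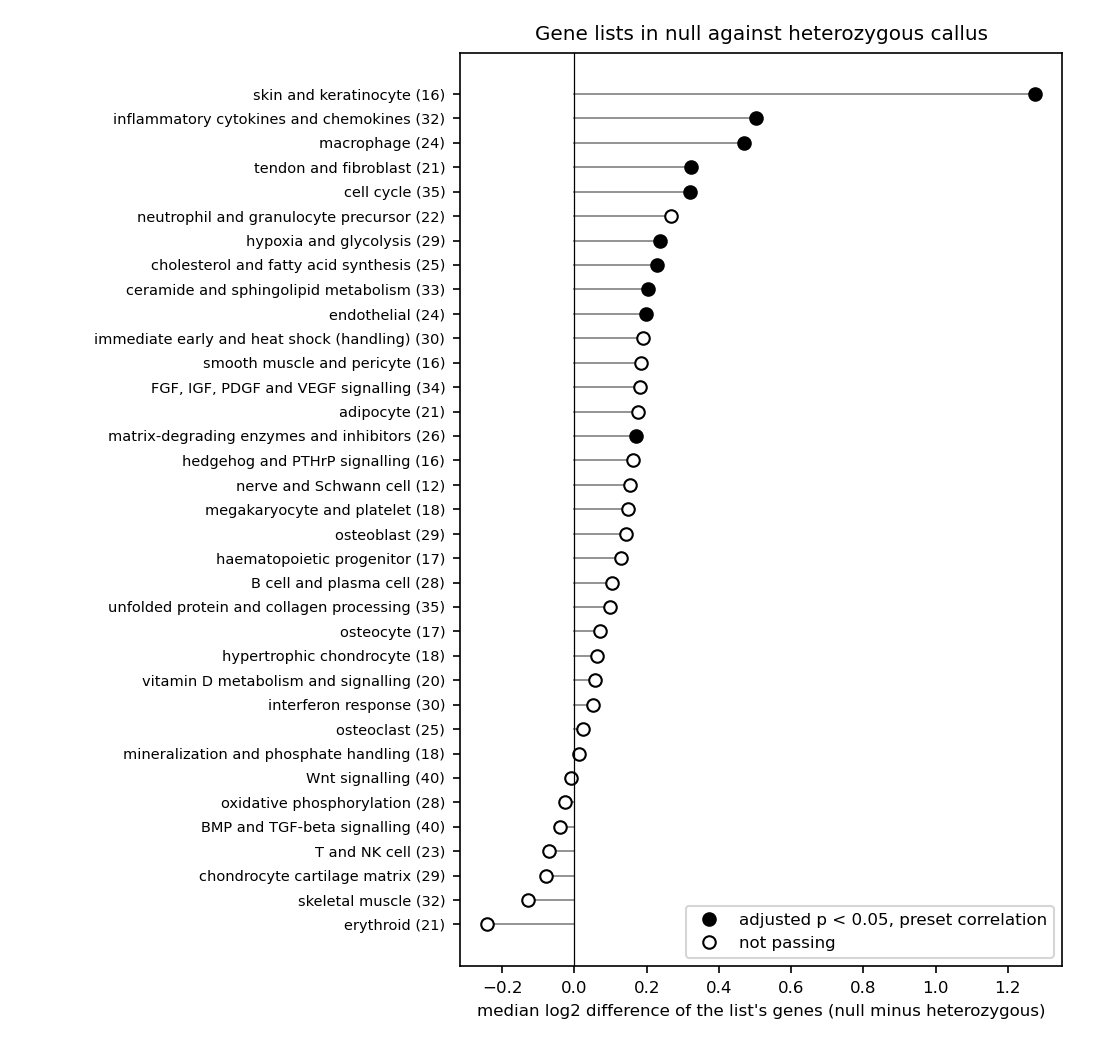
Median log2 difference, null minus heterozygous (horizontal axis), of the genes of each of 35 lists, with the number of measured genes in parentheses; filled circles mark lists with an adjusted p under 0.05 in camera with a preset correlation and open circles the others. The 10 filled circles all lie to the right of 0, from 0.17 for matrix-degrading enzymes and inhibitors to 1.27 for skin and keratinocyte genes.

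The lists of cartilage and bone formation did not pass. Chondrocyte cartilage matrix genes were lower in null callus in 17 of 29 cases (median -0.08, adjusted p = 0.689). The cartilage collagen gene Col2a1 averaged 8.16 ± 1.12 (SD, n = 3) in null and 9.27 ± 0.44 (SD, n = 3) in heterozygous callus (difference -1.11, -0.55 without null replicate 2 and -1.67 without null replicate 3), Snorc differed by -1.18 (SE 0.44), Col11a2 by -0.44 (SE 0.19; -0.27 without heterozygous replicate 3), and the matrix proteoglycan gene Prelp by 0.42 (SE 0.11). For hypertrophic chondrocyte genes the median was 0.06 and the mean -0.12, with a downward test direction (adjusted p = 0.689). Col10a1, the collagen of hypertrophic cartilage, stood at 3.11, 4.44 and 7.71 on the 3 null arrays and at 7.79, 6.74 and 7.35 on the heterozygous ones, a difference of -2.21 (SE 1.10; -1.22 without null replicate 1 and -3.52 without null replicate 3). Ibsp, which encodes bone sialoprotein, averaged 9.63 ± 0.19 (SD, n = 3) and 10.19 ± 0.22 (SD, n = 3), a difference of -0.56 (SE 0.16), and the alkaline phosphatase gene Alpl averaged 7.93 ± 0.07 (SD, n = 3) and 8.26 ± 0.09 (SD, n = 3), a difference of -0.32 (SE 0.10). The groups did not overlap for either gene, and neither passed limma's test (adjusted p = 0.999 for both). The osteoblast list had a median of 0.14 (adjusted p = 0.858). It passed upward without heterozygous replicate 3 (0.23, adjusted p = 0.00819) and without both marrow-poor arrays (0.29, adjusted p = 0.0300). Its collagen gene Col1a1 averaged 13.92 ± 0.21 and 13.89 ± 0.36. The citrate transporter gene Slc13a5 of the same list differed by -0.39 (SE 0.13). In the osteocyte list (adjusted p = 0.781), the median of 0.07 and the mean of -0.06 differ in sign. Its member Cd44, a hyaluronan receptor, averaged 10.08 ± 0.0049 and 9.55 ± 0.15 (difference 0.53, SE 0.11). Cd44 passed limma's test when adjusted over the list alone (adjusted p = 0.0424), but not over all probe sets (adjusted p = 0.999). The mineralization and phosphate handling list had a median of 0.01, a mean of -0.05 and a downward test direction (adjusted p = 0.583). Osteoclast genes had a median of 0.02 (adjusted p = 0.562), and the osteoclast protease gene Ctsk averaged 10.34 ± 0.52 and 10.29 ± 0.20. Without both marrow-poor arrays the osteoclast list passed camera upward (0.09, adjusted p = 0.0248).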

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

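The alternatives with a marrow score as a covariate and without null replicate 1 and heterozygous replicate 3, the marrow-poor arrays, were chosen after seeing the data; the other settings were chosen in advance. No paired analysis was possible because the labels give no litter or replicate numbers, and the numbers used here only name arrays. No probe set passed limma's test under any setting chosen in advance, and the lowest adjusted p ranged from 0.0614 for a plain test with equal variances to 1 without heterozygous replicate 1. With the marrow score as a covariate 1 probe set passed. The counts at an unadjusted p under 0.05 moved from 1660 to 746 with the filter at the median level, 771 with 1 probe set per gene, 4631 with array weights, 3552 with the marrow covariate and 3453 without both marrow-poor arrays, and from 1048 without null replicate 3 to 2721 without heterozygous replicate 3 when single arrays were left out. The filtered counts test fewer probe sets; the cause of the other moves was not tested. The 28 named probe sets gave 390 values on the same side under the alternatives and 1 reversal, Tlcd3b 1454209_at, whose differences ran from -0.19 to 0.079 when single arrays were left out. None of them passed under any alternative, and the filter at the median level leaves no value for Cyp24a1. The difference of Cyp24a1 1418867_at ran from -0.17 to 0.10 when single arrays were left out.

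The 10 passing lists became 0 with an estimated correlation, 0 with fry, 19 with the marrow covariate and 19 without both marrow-poor arrays, and 0 for these last settings with an estimated correlation; when single arrays were left out the count ran from 8 (without heterozygous replicate 2) to 21 (without null replicate 1). It was 10 with quantile normalisation, 10 with cyclic loess, 14 with arrays centred, 13 with array weights, 11 with the intensity trend, 8 with the filter, 13 with the mean of a gene's probe sets and 15 on ranks. Macrophage, skin and keratinocyte, inflammatory, hypoxia and glycolysis, and cholesterol and fatty acid synthesis lists passed under every setting with a preset correlation, with medians from 0.19 to 0.80, 0.75 to 1.85, 0.29 to 0.57, 0.11 to 0.29 and 0.15 to 0.29. Over all 35 lists and settings, 538 values kept their test direction and their side of the threshold, 65 kept the direction and passed newly, 53 kept it and no longer passed, and 44 changed direction, of which 4 passed newly and 1 no longer passed. The medians of lists whose test direction turned were 0.012 for oxidative phosphorylation with cyclic loess. With array weights they were 0.060 for oxidative phosphorylation, 0.073 for hypertrophic chondrocyte and -0.059 for interferon response. Without both marrow-poor arrays, with either correlation, they were 0.054 for oxidative phosphorylation, 0.20 for hypertrophic chondrocyte, -0.039 for mineralization and phosphate handling and 0.032 for Wnt signalling. The hypertrophic chondrocyte median, 0.06 as reported, stayed above 0 in these settings while its test turned from down to up, and the mineralization median went from 0.01 to below 0 while its test turned up. Ranges of the median when single arrays were left out were -1.26 to 1.59 for neutrophil, -1.17 to 0.78 for erythroid, -0.47 to 0.46 for megakaryocyte, -0.069 to 0.33 for B cell, -0.082 to 0.072 for T and NK cell, -0.11 to 0.49 for adipocyte, -0.23 to 0.38 for interferon, -0.0066 to 0.53 for cell cycle, -0.068 to 0.13 for hypertrophic chondrocyte, -0.15 to -0.00017 for chondrocyte cartilage matrix, -0.018 to 0.23 for osteoblast, -0.080 to 0.081 for osteocyte, -0.027 to 0.10 for osteoclast, -0.19 to 0.043 for skeletal muscle, -0.046 to 0.20 for unfolded protein, -0.097 to 0.085 for oxidative phosphorylation, 0.018 to 0.21 for immediate early, 0.074 to 0.38 for smooth muscle and pericyte, 0.0076 to 0.33 for haematopoietic progenitor, 0.0076 to 0.30 for nerve and Schwann cell, 0.036 to 0.24 for hedgehog and PTHrP, 0.085 to 0.23 for FGF, IGF, PDGF and VEGF and -0.052 to -0.019 for Wnt signalling genes. The cause was not tested for these. Of the lists that did not pass as reported, smooth muscle and pericyte passed in 8 of 16 settings with a preset correlation, hedgehog and PTHrP and immediate early in 7 each, FGF, IGF, PDGF and VEGF and skeletal muscle in 6 each, haematopoietic progenitor in 5, and adipocyte, nerve and Schwann cell, neutrophil and erythroid in 4 each; without both marrow-poor arrays the adipocyte (median 0.62, adjusted p = 4.13e-08) and smooth muscle lists (0.46, adjusted p = 4.25e-05) had their lowest p. The share of neighbours of Cyp24a1 at an unadjusted p under 0.05, 5.01% within 20 Mb, turned from above to below that of other genes with array weights (12.1% against 12.2%), the marrow covariate (9.23% against 10.3%), without both marrow-poor arrays (8.18% against 9.61%) and within 5 Mb (3.75% against 4.53%). When single arrays were left out it ran from 1.85% (against 2.83%, without null replicate 3) to 7.12% (against 7.81%, without heterozygous replicate 3), and it stayed above that of other genes only without heterozygous replicate 1 (3.17% against 2.96%); no Fisher test of these passed. Signal over background limits the weakly expressed genes, among them Il6 and Cyp24a1, which lie near the low end of the arrays.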

Other observations

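The tests of the muscle genes on null replicate 1, of the skin genes, of the other marrow lists and of RNA degradation array by array were chosen after the values were seen. The lists of denervated or regenerating muscle genes and of simple epithelial genes were also added after seeing the data. Among the signalling lists, which did not pass camera as reported, BMP and TGF-beta genes had a median difference of -0.04 (adjusted p = 0.434) with members on both sides. Gdf5, a joint and cartilage growth factor, averaged 4.81 ± 1.23 (SD, n = 3) in null and 6.88 ± 0.88 (SD, n = 3) in heterozygous callus, the BMP antagonist gene Chrdl2 differed by -0.58 (SE 0.13), follistatin (Fst) by -0.47 (SE 0.16) and the matrix gene Tgfbi by 0.76 (SE 0.29; 0.50 without null replicate 1). Wnt signalling genes had a median of -0.01 (adjusted p = 0.520), with the ligand Wnt5b at -0.48 (SE 0.17) and the antagonist Frzb at -0.38 (SE 0.14). Hedgehog and PTHrP genes had a median of 0.16 (adjusted p = 0.0526), and passed without null replicate 2 (0.24, adjusted p = 0.00343) and without heterozygous replicate 3 (0.24, adjusted p = 0.00194). Growth factor genes of the FGF, IGF, PDGF and VEGF families had one of 0.18 (adjusted p = 0.0501), and passed without null replicate 1 (0.17, adjusted p = 0.0417) and without heterozygous replicate 3 (0.23, adjusted p = 0.00230), with the lymphatic growth factor Vegfc at 0.50 (SE 0.13). With all arrays, the hedgehog and growth factor lists passed camera with array weights (adjusted p = 0.00529 and 0.0120). They also passed on ranks (adjusted p = 0.0293 and 0.0425) and with arrays centred (adjusted p = 0.0477 and 0.0371). The hedgehog list passed with the marrow covariate as well (adjusted p = 0.0179). The interferon response list had a median of 0.05 (adjusted p = 0.689), and passed upward without null replicate 2 (0.38, adjusted p = 0.0167) and without heterozygous replicate 3 (0.36, adjusted p = 0.0116) and downward without heterozygous replicate 2 (-0.23, adjusted p = 0.00141), with the interferon-inducible GTPase Irgm1 at -0.55 (SE 0.16). The unfolded protein and collagen processing list had one of 0.10 (adjusted p = 0.343; 0.20, adjusted p = 0.00702 without heterozygous replicate 3), with the cation channel gene Tmem38b at -0.64 (SE 0.16). The immediate early and heat shock list had one of 0.19 (adjusted p = 0.0501), and passed without null replicate 1 (0.21, adjusted p = 0.00374), null replicate 3 (0.19, adjusted p = 0.00172) and heterozygous replicate 2 (0.21, adjusted p = 0.0341), with Jun at -0.63 (SE 0.21) and Klf4 at 0.62 (SE 0.23), and oxidative phosphorylation genes one of -0.03 (adjusted p = 0.689), which passed upward without null replicate 1 (0.085, adjusted p = 0.0231) and downward without null replicate 3 (-0.097, adjusted p = 0.0189).

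Probe set 1447360_at, which has no gene symbol in the annotation used here, averaged 2.77 ± 0.56 (SD, n = 3) in null and 6.08 ± 0.37 (SD, n = 3) in heterozygous callus, and it was the 1 probe set that passed with the marrow score as a covariate (limma adjusted p = 0.0120, against 0.775 without it). Its null values (2.29 to 3.39) lay within those of sex-linked transcripts on arrays without them (1.77 to 3.52), so its level there was not above background and only a bound is given. Against 3.52 the heterozygous mean was 5.86-fold higher, without a measure of error. Genes within 20 Mb of Cyp24a1, which could carry sequence from the targeted line, were also compared: 19 of 379 (5.01%) had an unadjusted p under 0.05, against 797 of 17651 other genes (4.52%; two-sided Fisher's exact test p = 0.617), and 0 had an adjusted p under 0.05.

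The first pattern weighed was the lower level of Krt8 and Krt18 in null callus. Simple epithelium in the heterozygous samples is argued against by 17 other genes of gland, duct and mesothelium, whose median difference was 0.064 (95% bootstrap interval over genes -0.03 to 0.23) and of which 2 lay above the median level of all probe sets, while abundant epithelial transcripts stayed low in both groups, as in Krt19 (3.98 and 4.04) and Epcam (4.70 and 4.67). Skin there is argued against by the skin and keratinocyte genes, which were higher in null callus (median 1.27, interval 0.73 to 1.63). More damaged or denervated muscle in the heterozygous samples stays open as a candidate. Of 26 genes of denervated or regenerating muscle, 19 were lower in null callus (median -0.75, interval -0.95 to -0.30). The camera p was 5.83e-07 at the preset correlation and 0.0595 with an estimated one, and the fry p was 0.0863. The interval resamples genes and does not measure the spread between samples, and the preset correlation treats the genes as nearly independent. Lower genes included Gadd45a (9.19 and 10.83), Myod1 (8.59 and 9.86) and the abundant Sln (12.47 and 13.55). The embryonic or regeneration sarcomere genes Myh3, Myh8, Actc1, Tnnt2 and Myl4 were not lower (differences 0.23, 0.60, 0.37, 0.26 and 0.21, each within its SE). This part of the list does not support the candidate. The list was added after seeing the data, and 2 of the 26, Gdf5 (-2.07) and Runx1 (-1.01), are also in the lists fixed beforehand. On null replicate 1 the 26 muscle genes lay close to the heterozygous mean (median -0.066, interval -0.77 to 0.37), which leaves that array undecided. Their mean there (0.23) lay above that on heterozygous replicate 2 (0.039), while Krt8 (7.47 against 9.65) and Krt18 (7.74 against 10.17) lay below. A difference by genotype itself stays open and was not separated from muscle content. Chance stays open too, since both genes were named for their low unadjusted p. Neither Krt8 nor Krt18 passed limma's test (adjusted p = 0.775 for both).

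The second pattern was the low level of marrow genes on null replicate 1 and heterozygous replicate 3. On heterozygous replicate 3, RNA degradation is argued against by the difference between 3' and 5' probe sets of Gapdh, which lay 0.12 below the highest of the other 4 arrays (-0.1184; their SD 0.0605), and by that of beta-actin (-0.183; their SD 0.102). On null replicate 1 both differences were the highest of the 6 arrays, by 0.0748 and 0.0459, so degradation stays open there, and the mean of both arrays (-0.0218 from the highest other for Gapdh) decides nothing because it lies within the spread. Less bone marrow in these samples may account for the pattern, since all 3 further marrow lists (megakaryocyte, B cell and progenitor) were lower on both arrays than on each of the other 4, but the low level was not confined to marrow genes, as the skeletal muscle list was also lower there (-0.47 and -0.37) than on each of the others (lowest 0.043). Null replicate 1 and heterozygous replicate 3 come from different genotypes, and no biological explanation by genotype was tested.

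The third pattern was the higher level of inflammatory cytokine and chemokine genes in null callus. A difference in marrow content between the groups, as far as the marrow score measures it, is argued against. The score differed by 0.03 between the groups, against an SD of 1.82 over the arrays. Its 2 parts went opposite ways, with mean differences of 0.26 for the neutrophil and -0.20 for the erythroid list. The mean difference of the inflammatory list was 0.494 without and 0.497 with the score as a covariate, a ratio of 1.01. Because the score hardly differs between the groups, as a covariate it moves no group difference. The bound of 0.8 set on this ratio beforehand would then be met in any case, so the ratio adds nothing. Without both marrow-poor arrays the median of the list was 0.29 against 0.50 with them, and the list passed camera at the preset correlation (adjusted p = 0.000443) and not at the estimated one (adjusted p = 0.578). A larger macrophage share in null callus stays open. With the macrophage list mean as a covariate, which differed by 0.54 between groups, the mean difference fell to 0.192, a ratio of 0.388. That covariate comes from the same arrays and differs between the groups. It would shrink the difference of any list with a like pattern over the arrays, whatever the cause, so the ratio does not decide. Whether genotype changes macrophage content or the expression of these genes cannot be read from whole callus.

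The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 0 probe sets past the threshold, and the highest of the other splits gave 6; no split can give fewer than 0, so that 10 of the 10 reach that count by construction and the comparison says nothing about chance. For lists, the real split gave 10, 8 of the 10 splits gave as many, and the highest other gave 18, while 0 lists passed in any split with an estimated correlation. At the preset correlation the count of passing lists therefore does not set genotype apart from other splits of the arrays. The split that set null replicates 1 and 3 and heterozygous replicate 3 against the rest had 6942 probe sets at an unadjusted p under 0.05, against 1660 for the real one, which points to a structure of the samples other than genotype. It put both marrow-poor arrays (marrow scores -2.24 and -2.44) on one side. Null replicate 3, the remaining array there, had the lowest marrow score of the others (0.81).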
